A study of Mus musculus with 4 samples.

How the data were processed

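RNA was measured in 4 sorted fractions of mouse leukaemia cells, c-Kit- NS-GFP low, c-Kit- NS-GFP middle, c-Kit+ NS-GFP middle and c-Kit+ NS-GFP high, with 1 array per fraction and no replicates. RNA was extracted with TRIzol and biotin-labelled cRNA was hybridised to Affymetrix mouse arrays of 45101 probe sets. Per the submitters' processing notes, GCOS 1.2, MAS5 and R 3.0.2 were used, without a statement of which made which table. The first deposited table holds intensity, a linear MAS5-type signal per probe set. The second deposited table holds log2 values of 17419 probe sets, including 51 controls. Its values equal the log2 of the first table's signals plus 1 constant per array (0.42, 0.65, 0.49 and 0.44 from c-Kit- low to c-Kit+ high, equal within an array to 9.99e-09 on the log2 scale). These constants bring each array's trimmed mean over the probe sets of the second table to 500. No column of either table was left unused. A cell number in the labels was not used.

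The linear signals of the 45037 probe sets that are not controls were taken from the first table. Their trimmed means, leaving out 2% of values at each end, were 120, 99.0, 111 and 113, and the highest exceeded the lowest by 21.5%. The rule fixed at the start kept the authors' scaling only for a difference of up to 10%, so the signals were quantile normalized. They were floored at the 50th percentile (15.3, the same for each array after normalization) and taken to log2. Of these probe sets, the platform annotation lists 34945 with 1 gene, 932 with several genes and 9160 without a gene listed. Of those with 1 gene, 34741 were matched by gene ID to the symbols of the mouse reference annotation and 204 kept the symbol of the platform. Each gene was represented by its probe set with the highest mean signal, which gave 18193 genes. Probe sets with several genes were left out of the comparisons.

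The comparisons were c-Kit+ high against c-Kit- low (both ends of the sort), c-Kit+ middle against c-Kit- middle (c-Kit status at the middle gate), c-Kit+ high against c-Kit+ middle and c-Kit- middle against c-Kit- low (NS-GFP level within each c-Kit status). Genes at or below the floor on both arrays were left out of a comparison, and a gene above it on 1 array only has a lower bound on its fold. Genes were also counted as set apart in a fraction when at least 2-fold above or below each other fraction, and by the order of their signals among the 24 possible ones. Both NS-GFP contrasts were correlated across the genes above the floor on all 4 arrays, and the overlap of their genes past 2-fold was set beside the number expected of independent lists. With 1 array per group no test across samples can be run. The precision is limited by the number of arrays.

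The only repeat measurement is a second probe set for the same gene, which covers probe error and not differences between sorts or animals. Over the genes with a second probe set above the floor on both arrays (4382 to 4554 genes per comparison), the SD of a single probe set's log2 ratio was 0.48 for c-Kit+ high against c-Kit- low, 0.37 for c-Kit+ middle against c-Kit- middle, 0.30 for c-Kit+ high against c-Kit+ middle and 0.37 for c-Kit- middle against c-Kit- low. Of genes whose brightest probe set was past 2-fold, the second had the same sign in 94.6%, 90.5%, 86.4% and 92.0% of cases, in that order. For c-Kit+ high against c-Kit+ middle this was 38 of 44 genes. Over all genes with a second probe set the sign was the same in 78.5%, 68.8%, 61.4% and 73.1%. The Pearson correlation of both ratios across genes was 0.80, 0.60, 0.30 and 0.68.

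The genes, lists, thresholds and rules below were chosen before the data were examined. Named genes were Kit, Gnl3, Hoxa9 and Meis1. For each comparison they were also the 8 with the highest and the 8 with the lowest log2 ratio among genes above the floor on both arrays, and in each direction the 3 with the brightest signal among genes at the floor on the other array. For c-Kit+ high set apart they were the 8 in each direction whose smallest ratio to the others was largest. Predicted or clone-named genes were passed over. From the lists, examples came from the 2 to 4 members furthest in the direction of the median and any member at least 2-fold the other way.

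The 33 gene lists cover sort and model genes, haematopoietic stem and progenitor genes, posterior Hoxa genes and Hox cofactors, targets linked to Hoxa9 and Meis1, myeloid transcription factors, primary granule genes, secondary and tertiary granule and late neutrophil genes, monocyte and macrophage genes, and eosinophil, basophil and mast cell genes. Other lineages are covered by erythroid, megakaryocyte, B cell, T and NK cell, MHC class II and dendritic cell, and marrow stroma and endothelium genes. Cell growth is covered by ribosome biogenesis, cytosolic ribosomal protein, Myc-linked, S phase, G2 and M phase, cell cycle inhibitor and quiescence, p53 target, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, and telomere and nucleostemin partner genes. The rest are interferon-stimulated, inflammatory, immediate early and stress, adhesion and homing, Fc receptor and phagocytosis, lysosome, and ABC transporter genes. Lists were written from general knowledge, some genes stand in more than 1 list, and members absent from the array or below the floor on every array were left out. A member at the floor on both arrays of a comparison counts as 0 in the median of its list, and so do such genes in the random lists. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on deciles of mean signal. A percentile of 100 means that no random list had a higher median. It describes these arrays and is not a test across samples, and genes of a list vary together.

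The alternatives were the authors' scaling as deposited, centring each array on its median over bright probe sets, floors at the 25th and 75th percentiles, no floor with 1 added before the log2, the mean of a gene's probe sets, leaving out probe sets shared between transcripts, the second deposited table, and thresholds of 1.5-fold and 4-fold. The authors' scaling means the signals of the first deposited table as they stand, whose trimmed means differed by up to 21.5%. Added after the data were seen were c-Kit- middle in place of c-Kit- low, and counts without the c-Kit- low array.

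The procedure was tested on simulated data with noise of the size seen between probe sets. Of genes planted at 4-fold it recovered 92% to 98% by comparison, and of those planted at 2-fold 38% to 58%. Of unchanged genes, 330 of 10657 passed 2-fold in the simulation of c-Kit+ high against c-Kit- low, 77 of 10628 in that of c-Kit+ middle against c-Kit- middle, 7 of 10450 in that of c-Kit+ high against c-Kit+ middle and 61 of 10514 in that of c-Kit- middle against c-Kit- low. A planted list reached percentile 100 in each. The noise had 1 SD per comparison, taken from genes with a second probe set above the floor and given to dim probe sets too. It held no differences between sorts or animals. The simulated counts of unchanged genes are therefore not an estimate of the errors within the real counts, least of all for dim genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.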

Results

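Gene expression was profiled in leukaemia cells sorted from the bone marrow of mice on the C57BL/6 background. The leukaemia, a model of acute myeloid leukaemia, arose from marrow into which HoxA9 and Meis1 had been introduced. These homeobox genes together transform myeloid progenitors. The donor marrow carried a reporter, NS-GFP, in which a region of the nucleostemin promoter drives green fluorescent protein. Nucleostemin, encoded by Gnl3, is a nucleolar GTPase abundant in stem cells and proliferating cells. c-Kit, encoded by Kit, is the receptor for stem cell factor and is carried by immature blood cells. The cells were sorted by both markers into 4 fractions, here called c-Kit- low, c-Kit- middle, c-Kit+ middle and c-Kit+ high after their c-Kit status and NS-GFP gate. The study's title ties nucleostemin promoter activity to a leukaemia stem cell signature and to outcome in patients, and the comparisons below describe how transcription differed along the sort.

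Each fraction was measured on 1 Affymetrix mouse array, giving 4 samples in 4 groups without replicates. No p-value, error or count of significant genes can therefore be given, and genes are described by the size of their difference. A gene was counted as higher or lower at a size of at least 2-fold, after quantile normalization and with signals below the floor of 15.3 set to it. Where 1 of the arrays lay at the floor, the fold is a lower bound. Of 18193 genes on the array, 11927 were above the floor in at least 1 fraction and 9144 in all 4. The number above it was 10332 in c-Kit- low, 10419 in c-Kit- middle, 10322 in c-Kit+ middle and 10437 in c-Kit+ high. Across genes, the log2 signals of c-Kit+ middle and c-Kit+ high had a Pearson correlation of 0.987, those of the c-Kit- fractions 0.957, and those of the ends of the sort 0.872. Genes are not independent replicates, so these coefficients describe the arrays. The 3' to 5' signal ratio of the Actb control probe sets was 2.5, 3.28, 3.98 and 4.70 from c-Kit- low to c-Kit+ high, whereas that of Gapdh was 3.37, 3.91, 3.10 and 3.41. For the added control transcripts it was, in the same order, 8.16, 11.9, 20.7 and 28.7 (lys), 5.91, 5.54, 7.52 and 13.8 (phe), 18.7, 19.3, 13.2 and 18.3 (thr) and 31.4, 38.4, 59.4 and 46.1 (dap).

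The genes of the sort were examined first. Kit had a signal of 690 in c-Kit+ middle and 479 in c-Kit+ high, against 26.4 in c-Kit- middle, and was below the floor in c-Kit- low. Gnl3 followed the NS-GFP gates, with signals of 183, 584, 1109 and 1299 from c-Kit- low to c-Kit+ high. It was 7.09-fold higher at the upper end of the sort than at the lower end (log2 ratio 2.83). Between the middle gates it was 1.90-fold higher in c-Kit+ than in c-Kit- cells, although the gates carry the same name. Hoxa9, a homeobox regulator of immature myeloid cells, went the other way, with signals of 1882, 786, 673 and 510. All 3 probe sets of Meis1 were below the floor on every array. Whether the Hoxa9 and Meis1 probe sets read the introduced genes is not given in the sources used here, so neither gene checks the labels.

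**Figure D1:**
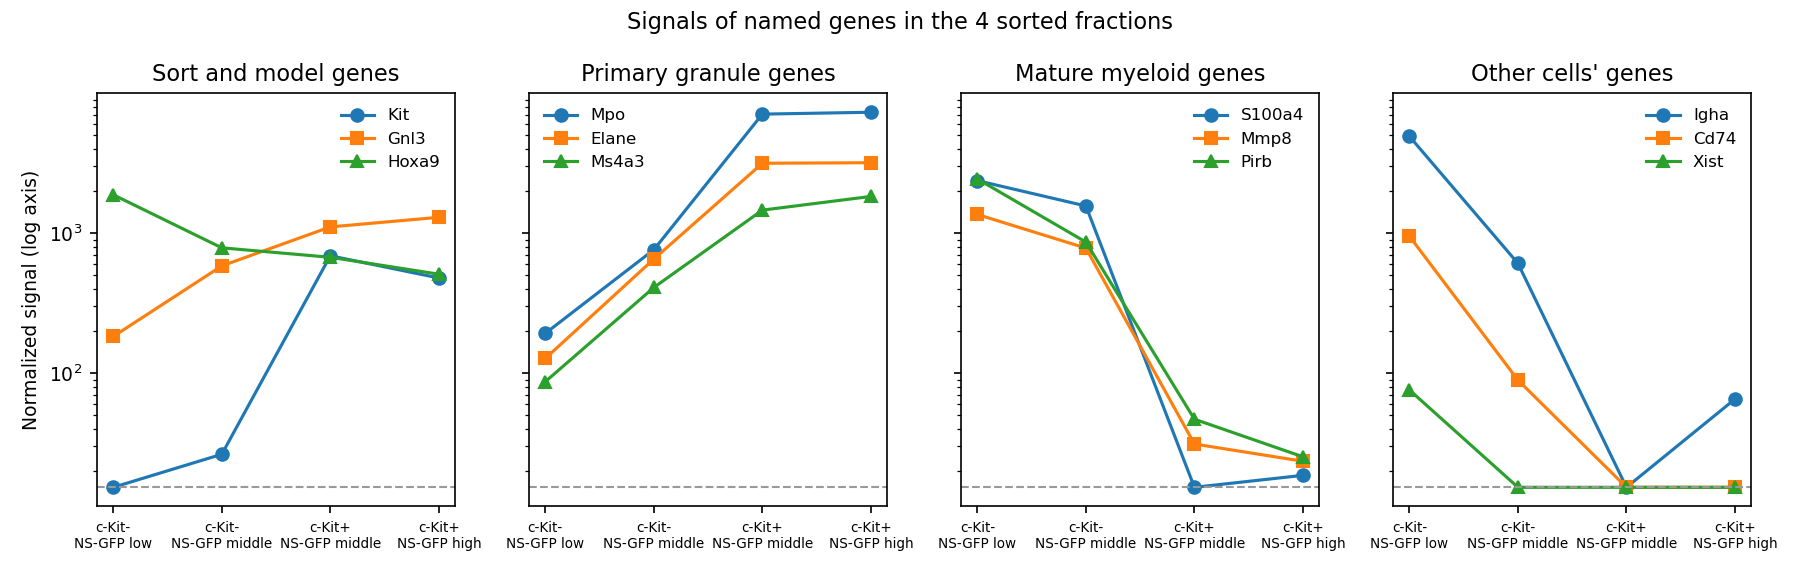
Normalized signal on a log axis of 12 genes in the 4 sorted fractions, 1 array each, with the floor of 15.3 as a dashed line and lower signals drawn on it. Kit is near the floor in both c-Kit- fractions, Mpo reaches 7309 in c-Kit+ high, S100a4 stands at 2374 in c-Kit- low and at the floor in c-Kit+ middle, and Igha stands at 4915 in c-Kit- low.

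The ends of the sort, c-Kit+ high and c-Kit- low, differ in both markers. In c-Kit+ high, genes of cell division were higher, as were 4 of 8 genes of the primary granule list. Of these, Mpo, Elane and Ms4a3 mark immature granulocytic cells, and the other was Calr (2.11-fold). Genes of mature neutrophils, monocytes and phagocytes were lower. Mpo, the peroxidase of primary granules, was 37.9-fold higher, Elane, neutrophil elastase, 25-fold, and Ms4a3, a gene of granulocyte and monocyte progenitors, 21.0-fold. Kif11, a mitotic kinesin, was 18.4-fold higher, as was Slc16a1, a lactate transporter. Shmt1, an enzyme of folate metabolism, was 22.5-fold higher, Rgcc, a regulator of the cell cycle, 27.6-fold, and Lrr1 16.7-fold. The Shmt1 signal in c-Kit- low was 15.6, close to the floor of 15.3, so the floor nearly sets its fold. Genes at the floor in c-Kit- low included Kit (at least 31.2-fold), Mgam, a maltase-glucoamylase (at least 34.5-fold), and Dio2, a thyroid hormone deiodinase (at least 30.2-fold).

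On the other side, S100a4, a calcium-binding protein of motile myeloid cells, was 127-fold lower in c-Kit+ high than in c-Kit- low. Lifr, the receptor for leukaemia inhibitory factor, was at least 193-fold lower. Pirb, an inhibitory receptor of myeloid and B cells, was 96.4-fold lower, and Mmp8, neutrophil collagenase, 57.8-fold. Niban1 was 67.9-fold lower, the scaffold gene Ahnak 63.2-fold, Ptger4, a prostaglandin E receptor, 58.7-fold, and Zfp36l1, a factor that promotes mRNA decay, 44.2-fold. In c-Kit+ high the signals of S100a4 (18.7), Ptger4 (16.8) and Zfp36l1 (16.15) were close to the floor. The lectin gene Clec4a3 was at least 99.8-fold lower and Plbd1, a phospholipase gene, at least 97.0-fold. Igha, which encodes the constant region of IgA, was 75.1-fold lower.

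By list, the 37 measured genes of the G2 and M phases were all higher in c-Kit+ high than in c-Kit- low, with a median log2 ratio of 2.73, above each of 10000 random lists of matched signal (percentile 100). Examples besides Kif11 were Ttk, a spindle checkpoint kinase (13.7-fold), Cdk1, the mitotic cyclin-dependent kinase (13.6-fold), and the kinetochore gene Nuf2 (12.8-fold). Of 35 S phase genes, 32 were higher (median 2.07, percentile 100), among them Ccne2, a cyclin of the G1 to S transition (10.1-fold), and Rrm2, a ribonucleotide reductase subunit (8.34-fold). Of 71 ribosome biogenesis and nucleolar genes, to which Gnl3 belongs, 46 were higher (median 1.24, percentile 100), including the snoRNP gene Nop58 (10.3-fold) and Wdr12 (6.78-fold). Of 31 Myc-linked growth genes, 25 were higher (median 1.68, percentile 100), including Ppat, which starts purine synthesis (9.55-fold), and Odc1, which starts polyamine synthesis (7.58-fold). The list of telomere genes and nucleostemin partners had 7 of 11 higher (median 1.51), with the DNA repair genes Brca1 (7.76-fold) and Brca2 (4.46-fold) and the telomere-binding Terf1 (3.98-fold). Of 57 oxidative phosphorylation genes 6 were higher (median 0.46, percentile 99.7), and the median of 43 cytosolic ribosomal protein genes was 0.06, at percentile 43.6. With c-Kit- middle in place of c-Kit- low these differences were smaller. Then 4 of the 37 G2 and M phase genes were past 2-fold (median 0.52), as were 4 of 35 S phase genes (median 0.46), 16 of 71 ribosome biogenesis genes (0.70), 7 of 31 Myc-linked genes (0.74), 3 of 11 telomere genes and partners (0.65) and 0 of 57 oxidative phosphorylation genes (0.09, percentile 90.4, within the range of random lists).

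The lists of mature myeloid function were lower in c-Kit+ high. Of 24 secondary granule, tertiary granule and late neutrophil genes 16 were lower (median -1.45, percentile 0), such as Ifitm6 (28.8-fold), the gelatinase gene Mmp9 (at least 22.2-fold) and Ltf, lactoferrin (15.2-fold), while the ficolin gene Fcnb was 2.06-fold higher. Of 20 monocyte and macrophage genes 14 were lower (median -1.82, percentile 0), including Tlr7 (at least 26.6-fold) and Apoe (18.5-fold), and the adhesion molecule gene Vcam1 was at least 7.05-fold higher. Of 24 Fc receptor, phagocytosis and NADPH oxidase genes 19 were lower (median -1.47, percentile 0), with Tlr13 32.7-fold and the Src-family kinase gene Fgr 13.9-fold lower. Of 22 inflammatory and NF-kappaB-linked genes 16 were lower (median -1.82, percentile 0), with Socs3, a feedback inhibitor of cytokine signalling, at least 33.7-fold and the chemokine gene Cxcl2 15.1-fold lower. Adhesion and homing genes had 11 of 22 lower (median -0.94), led by the formyl peptide receptor gene Fpr2 (at least 70.2-fold) and the integrin genes Itgb2 (8.05-fold) and Itgam (7.13-fold). Lysosome genes had 12 of 27 lower (median -0.75), with the protease genes Lgmn at least 9.59-fold and Ctss 4.76-fold lower and Gla 3.15-fold higher. Of 12 myeloid transcription factors 6 were lower (median -0.99, percentile 0.09), including Id2 (14.8-fold), Irf5 (9.23-fold) and Klf4 (5.67-fold), whereas Gfi1, a repressor needed for granulocyte formation, was 16-fold higher. Against c-Kit- middle in place of c-Kit- low, 10 late neutrophil genes were lower (median -0.51), 13 monocyte and macrophage genes (-1.26), 9 Fc receptor, phagocytosis and oxidase genes (-0.95), 11 inflammatory genes (-1.14), 7 adhesion genes (-0.57), 4 lysosome genes (-0.47) and 3 myeloid transcription factors (-0.62).

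Genes of arrest and stress were also lower at the upper end of the sort. Of 16 cell cycle inhibitor and quiescence genes 9 were lower (median -1.24, percentile 0), such as Btg2 (5.89-fold), Pink1 (4.56-fold) and Txnip (3.76-fold), and 3 were higher, namely Rbl1 (4.16-fold), Cdkn1c (at least 4.05-fold) and Cdkn2c (2.03-fold). Immediate early and stress genes had 11 of 22 lower (median -0.83, percentile 0.01), among them Ier5 (6.09-fold) and Junb (5.71-fold), with the chaperone gene Hsp90aa1 2.81-fold higher. Interferon-stimulated genes had 14 of 32 lower (median -0.88, percentile 0), among them Irf7 (at least 8.28-fold) and Mx1 (7.92-fold), with Gbp3 7.72-fold higher. With the floor at the 75th percentile the interferon median was -0.17 (percentile 11.4), within the range of random lists. Haematopoietic stem and progenitor genes did not stand apart from random lists (median 0.45, percentile 95.5). The chromatin genes Hmgb3 (5.11-fold) and Cbx5 (4.36-fold) led the 8 higher members of 20, and the receptor gene Flt3 (2.13-fold) and Prdm16 (at least 2.44-fold) were lower. Much of this paragraph rests on the c-Kit- low array. Against c-Kit- middle, 1 of 22 immediate early and stress genes was lower (median -0.23, percentile 1.58), 5 of 32 interferon-stimulated genes (-0.22, percentile 0.74) and 6 of 16 inhibitor and quiescence genes (-0.77), while 4 of 20 stem and progenitor genes were higher (0.37, percentile 99.4).

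The c-Kit- low array also held signal of other blood lineages. Of 12 measured MHC class II and dendritic cell genes 8 were lower in c-Kit+ high (median -2.20, percentile 0), with Cd74 at least 62-fold and H2-Aa 24-fold lower. T and NK cell genes had 5 of 10 lower (median -0.87), with the chemokine gene Ccl5 at least 14.3-fold lower. B cell genes had 2 of 7 lower (median -0.34), namely Jchain (24.4-fold) and Cd22 (at least 8.55-fold), and erythroid genes 3 of 9 (median -0.01), namely Alas2 (at least 3.39-fold), Slc4a1 (at least 2.38-fold) and Tspan33 (at least 2.36-fold). Xist, the RNA of the inactive X chromosome, had a signal of 76.0 in c-Kit- low and was below the floor elsewhere. Against c-Kit- middle in its place, 4 class II and dendritic cell genes were lower (median -0.44) and none of the T and NK cell (0.00, percentile 36.0), B cell (-0.10, percentile 8.43) and erythroid genes (0.00). The B cell median also lay within the range of random lists with the floor at the 25th or 75th percentile, with no floor and with the mean of probe sets.

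In all, 1803 of 11288 genes were at least 2-fold higher in c-Kit+ high than in c-Kit- low and 1536 were lower, with 188 and 267 of these being lower bounds. The authors' own scaling turned this split, with 42.4% of the genes past 2-fold higher against 54% here, and moved the median of all genes from 0.09 to -0.08. The second deposited table gave 49.25%. With c-Kit- middle in place of c-Kit- low the counts were 538 and 721.

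**Figure D2:**
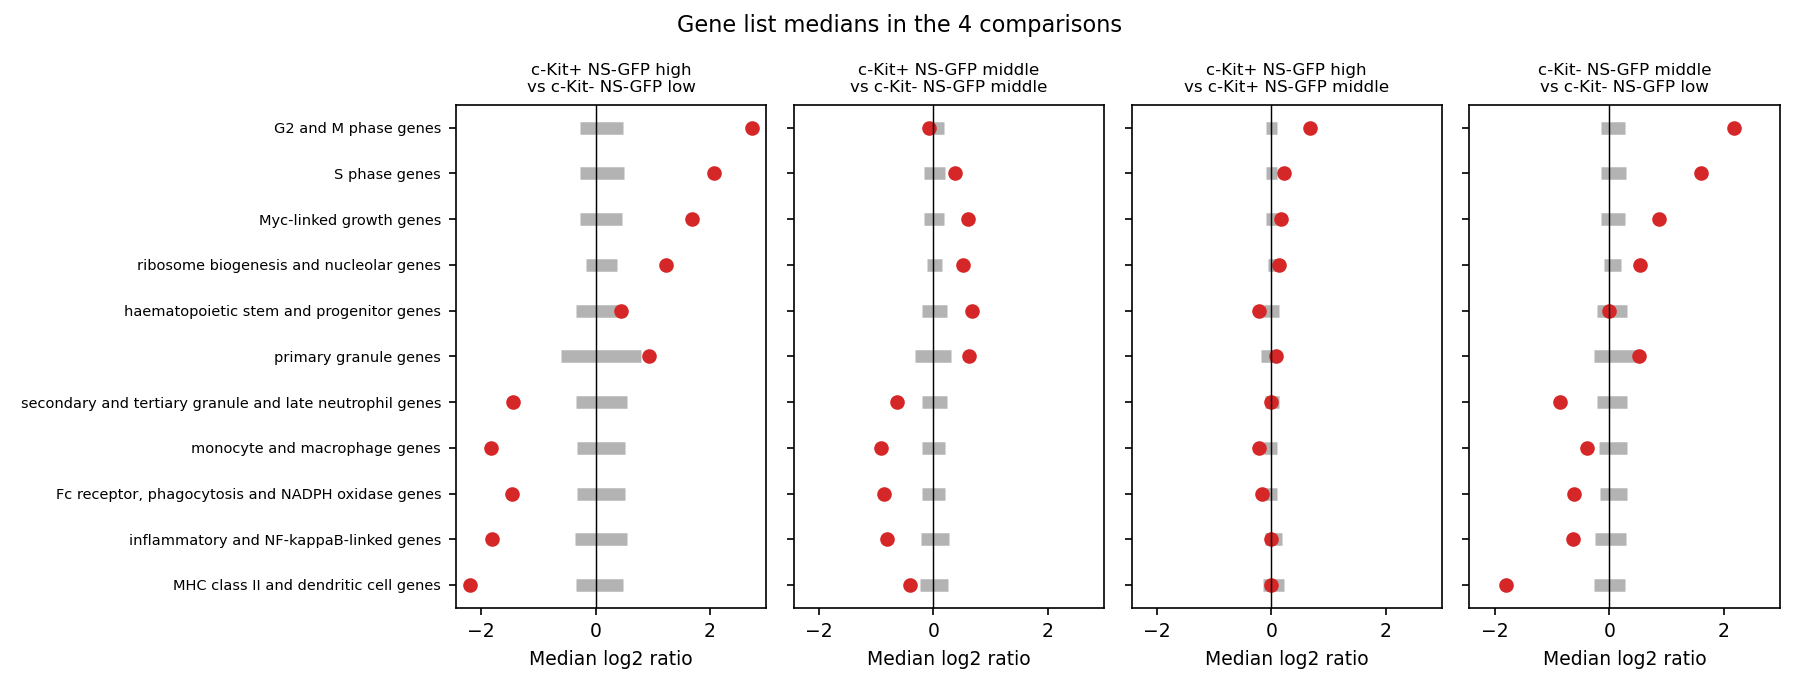
Median log2 ratio of 11 gene lists (points) in the 4 comparisons, with the central range of medians of 10000 matched random lists from the 2.5th to the 97.5th percentile as grey bars. G2 and M phase genes lie at 2.73, -0.08, 0.68 and 2.17 from left to right, and monocyte and macrophage genes at -1.82, -0.92, -0.21 and -0.39.

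Cells of the middle NS-GFP gate were compared by c-Kit status. In c-Kit+ middle, Kit was 26.2-fold higher than in c-Kit- middle, Mgam 21.2-fold, the oxidoreductase gene Vat1 10.3-fold, Dio2 9.84-fold and Mpo 9.29-fold. Egln3, an oxygen-sensing prolyl hydroxylase, was 7.13-fold higher, Slc16a1 6.73-fold and Vcam1 5.96-fold. Hdc, the histamine-forming enzyme, was at least 9.98-fold higher, Far2 at least 7.69-fold and Tmem191c at least 6.70-fold. Mature myeloid genes were lower in the c-Kit+ cells. Lifr was 29.2-fold lower, S100a6 29.2-fold, Mmp8 25.1-fold, the matrix genes Tgfbi and Vcan 21.7-fold and 21.6-fold, Pirb 18.4-fold, the semaphorin and VEGF co-receptor gene Nrp1 17.5-fold and Lpl, lipoprotein lipase, 16-fold. S100a4 was at least 102-fold lower and Clec4a3 at least 33.3-fold. Igha, a gene of plasma cells, was at least 39.7-fold lower, with a signal of 609 in c-Kit- middle, where H2-Aa had 254 and Cd74 89.3.

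G2 and M phase genes did not separate these fractions as they did the ends of the sort. None of the 37 G2 and M phase genes reached 2-fold in either direction between c-Kit+ middle and c-Kit- middle (median -0.08, percentile 13.6; 0.08 under the authors' scaling), the most different being Prc1, a gene of the central spindle (1.62-fold lower). S phase genes had 2 of 35 higher and 31 with a log2 ratio above 0 (median 0.37, percentile 99.99). The 2 were Uhrf1 (3.08-fold) and Hells (2.34-fold), both of which help to maintain DNA methylation. Ribosome biogenesis genes had 8 of 71 higher (median 0.52, percentile 100), including Wdr43 (2.99-fold) and Nop16 (2.56-fold), and Myc-linked genes 5 of 31 (median 0.60, percentile 100), including Odc1 (2.72-fold) and Myc itself (2.35-fold). Stem and progenitor genes had 8 of 20 higher and none lower (median 0.67, percentile 100), led by Cd27 (3.26-fold), Angpt1 (3.10-fold), Sox4 (3.07-fold) and Myb (2.65-fold). Of 8 primary granule genes 3 were higher (median 0.61), namely Mpo, Elane (4.83-fold) and Ms4a3 (3.57-fold). Of 8 eosinophil, basophil and mast cell genes 4 were higher (median 0.86, percentile 100). Besides Hdc these were Cpa3, a mast cell carboxypeptidase (5.76-fold), Ms4a2, an IgE receptor chain (at least 3.29-fold), and Siglecf, an eosinophil receptor (3.09-fold). This last list depended on the floor, its median being 0.10 at percentile 66.0 with the floor at the 25th percentile and 0.51 at percentile 97.0 with no floor.

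Lists of mature myeloid genes were lower in c-Kit+ middle than in c-Kit- middle. They comprised 10 of 24 late neutrophil genes (median -0.64, percentile 0), 9 of 20 monocyte and macrophage genes (median -0.92, percentile 0), 11 of 24 Fc receptor, phagocytosis and oxidase genes (median -0.86, percentile 0) and 10 of 22 inflammatory genes (median -0.82, percentile 0). Examples were Ifitm6 (7.47-fold lower), Ltf (5.35-fold), Tlr7 (7.78-fold), Tlr13 (5.33-fold) and Cd40 (at least 11.6-fold). Of 12 myeloid transcription factors 4 were lower (median -0.52, percentile 0.07), led by Id2 (8.68-fold), and Gfi1 (4.42-fold) and Egr1 (2.36-fold) were higher. Of 16 cell cycle inhibitor and quiescence genes 5 were lower (median -0.43, percentile 0.07), led by Cdkn1a, which encodes p21 (5.43-fold), and Foxo1 (3.22-fold). Of 12 MHC class II and dendritic cell genes 4 were lower (median -0.42, percentile 0.17), and this median was 0, within the range of random lists, with the floor at the 75th percentile and without shared probe sets. In total 389 of 11094 genes were higher and 584 lower, 59 and 119 of them as bounds. The authors' scaling turned this split, with 57.2% of genes past 2-fold higher against 40.0% here, and moved the median of all genes from 0.02 to 0.17. The second deposited table, with its own scaling, gave 41.9%.

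The NS-GFP level among c-Kit+ cells was examined in c-Kit+ high against c-Kit+ middle, the closest fractions of the sort. The Actb 3' to 5' ratio was 4.70 and 3.98 in these fractions. A second probe set had a log2 ratio of the same sign in 61.4% of 4554 genes. Genes of the G2 and M phases were shifted upward in c-Kit+ high, most of them by less than 2-fold. Of 37 G2 and M phase genes 4 were at least 2-fold higher and none lower, with a median of 0.68 (percentile 100), and all 37 had a log2 ratio above 0. The 4 were the kinetochore gene Ndc80 (2.15-fold), Cdk1 (2.06-fold), Prc1 (2.05-fold) and Hmmr, a spindle and hyaluronan-binding protein (2.03-fold). S phase genes had a median of 0.21 (percentile 100), with 25 of 35 above 0 and none past 2-fold. Bcl2l11, which encodes the pro-apoptotic BH3-only protein Bim, was 3.43-fold lower in c-Kit+ high, Cpa3 3.31-fold, Ahnak 3.19-fold, the stress gene Gadd45g 3.03-fold, the bacterial RNA sensor Tlr13 2.99-fold, Bmf, another BH3-only gene, 2.99-fold, Rap1gap2 2.98-fold and Acap3 2.85-fold. The protein kinase C gene Prkch was at least 3.25-fold lower, the retinoic acid receptor gene Rarg at least 3.03-fold and Tmc4 at least 2.94-fold.

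Genes higher in c-Kit+ high than in c-Kit+ middle were mostly dim. Troap, a spindle-associated gene, was 3.14-fold higher, Fgfrl1 3.02-fold, Casp14 2.98-fold, Thoc2l 2.86-fold, the mediator subunit gene Med18 2.86-fold, the mevalonate kinase gene Mvk 2.84-fold, H2-Aa 2.71-fold and Praf2 2.68-fold. Of these, Med18 had the highest signal, 315 in c-Kit+ high, and the others had 64.0 or less. Igha was at least 4.27-fold higher at a signal of 65.4, Pitpnm2 at least 3.06-fold and Zfp691 at least 2.85-fold. Small shifts with no or few genes past 2-fold were seen in ribosome biogenesis (median 0.14, percentile 99.99), oxidative phosphorylation (0.17, percentile 100) and, downward, in stem and progenitor genes (-0.21, percentile 0.08), monocyte genes (-0.21, percentile 0.08), targets linked to Hoxa9 and Meis1 (-0.24, percentile 0.03) and p53 targets (-0.27, percentile 0.03). Cd27, a TNF receptor family gene, was 2.17-fold lower and Hmga2, a chromatin gene of fetal stem cells, 2.23-fold higher among the stem and progenitor genes, and Trp53inp1 was 2.40-fold lower among the p53 targets. The stem and progenitor and p53 medians shrank to -0.055 and -0.091, within the range of random lists, when all probe sets of a gene were averaged. In total 110 of 11048 genes were higher and 109 lower, 40 and 37 of them as bounds. These totals became 10 and 12 with the floor at the 75th percentile, 1209 and 1163 with it at the 25th, and 1768 and 1751 with no floor. The share of genes past 2-fold that were higher was 50.2% here, 39.1% under the authors' scaling and 21.1% in the deposited log2 table, which leaves out most probe sets.

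The NS-GFP level among c-Kit- cells was examined in c-Kit- middle against c-Kit- low. All 37 G2 and M phase genes were higher in c-Kit- middle (median 2.17, percentile 100), as were 30 of 35 S phase genes (median 1.61, percentile 100). Kif11 was 11.7-fold higher, the condensin gene Ncapg 9.32-fold, the mitotic phosphatase gene Cdc25c 8.75-fold, and the kinetochore genes Spc25 and Nuf2 8.67-fold and 8.53-fold. Shmt1, close to the floor in c-Kit- low, was 8.55-fold higher, Prc1 7.85-fold and Cdk1 7.50-fold. Ncam1, a neural cell adhesion molecule also carried by some leukaemias, was at least 11.4-fold higher, Tmem178 at least 8.95-fold and the exonuclease gene Exo1 at least 4.93-fold. Ribosome biogenesis genes had 11 of 71 higher (median 0.53, percentile 100), including Nop58 (4.33-fold) and Lyar (2.98-fold), and Myc-linked genes 13 of 31 (median 0.87, percentile 100), including Ppat (4.15-fold) and Ung (4.12-fold).

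Among probe sets of 1 gene, those most strongly lower in c-Kit- middle than in c-Kit- low included several genes of lymphoid, plasma and antigen-presenting cells. Jchain, the joining chain of IgA and IgM, was 12.9-fold lower, the kappa variable gene Igkv8-30 11.6-fold, Cd74, the invariant chain of class II, 10.6-fold, Tspan13 8.72-fold, Igha 8.07-fold, the B cell receptor Cd22 7.96-fold, H2-Eb1 7.51-fold and the transcription factor gene Nfatc2 6.87-fold. Ccl5, a chemokine of T and NK cells, was at least 14.3-fold lower, Tent5c at least 9.27-fold and the dendritic cell integrin Itgax at least 8.32-fold. The Xist signal was 76.0 in c-Kit- low and below the floor in c-Kit- middle, as given above. MHC class II and dendritic cell genes had 7 of 12 lower (median -1.80, percentile 0) and T and NK cell genes 5 of 10 (median -0.99, percentile 0). B cell genes had 2 of 7 lower, Jchain and Cd22, with a median of 0.00 (percentile 51.5), and erythroid genes 2 of 9, Alas2 (at least 3.39-fold) and Slc4a1 (at least 2.38-fold), with a median of -0.12 (percentile 5.10). Medians of mature myeloid and inflammatory lists lay closer to 0 than those of the class II and of the T and NK cell lists. The median was -0.85 for late neutrophil genes (8 of 24 lower), -0.39 for monocyte and macrophage genes (5 of 20), -0.62 for Fc receptor, phagocytosis and oxidase genes (9 of 24) and -0.64 for inflammatory genes (9 of 22). Interferon-stimulated genes had 6 of 32 lower (median -0.46), led by the antiviral gene Rsad2 (4.2-fold), with Gbp3 2.93-fold higher. This median lay within the range of random lists with the floor at the 75th percentile (-0.17, percentile 5.3) and in the deposited log2 table (-0.25, percentile 4.1). In total 732 of 11067 genes were higher and 604 lower, 72 and 82 of them as bounds. The authors' scaling turned this split, with 23.0% of genes past 2-fold higher against 54.8% here, and moved the median of all genes from 0.03 to -0.27. The second deposited table, with its own scaling, gave 56.7%.

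The NS-GFP contrasts among c-Kit+ and c-Kit- cells share no array and were set side by side over the 9144 genes above the floor on all 4 arrays. Their log2 ratios had a Pearson correlation of 0.342 and a Spearman correlation of 0.319 across genes, which are not independent replicates. With no floor the Pearson value was 0.0571. At 2-fold, 12 genes were higher in both contrasts, against 3.67 for independent lists, and 19 were lower in both, against 2.97. Those higher in both included the division genes Cdc25c, Cdk1, Cdkn3, Gpsm2, Hmmr, Kifc1, Ndc80 and Prc1, together with Ddias, Hmga2, Msl3l2 and Wdr70. Those lower in both included Bcl2l11, Bmf, Cpa3, Gadd45g, Tlr13, Niban1, the cytokine gene Tgfb1, the autophagy receptor gene Sqstm1 and the platelet integrin gene Itgb3. These genes were chosen after their values were seen.

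Genes that set the c-Kit+ high fraction apart from every other were few at the main floor. Of 11927 genes, 29 were at least 2-fold higher there than in each other fraction and 55 were lower. The same counts were 476 and 622 for c-Kit- low, 8 and 14 for c-Kit- middle and 10 and 15 for c-Kit+ middle. Without the c-Kit- low array they were 472 and 263 for c-Kit- middle, 21 and 23 for c-Kit+ middle and 42 and 59 for c-Kit+ high. Among genes higher in c-Kit+ high alone, the smallest ratio over the others was 2.86-fold for Thoc2l and for Med18, at least 2.42-fold for Prg3, an eosinophil granule gene, 2.31-fold for Map2k3os, 2.29-fold for Casp14, 2.28-fold for Ccm2l, 2.27-fold for the cohesin acetyltransferase gene Esco2 and 2.24-fold for Fras1. On the lower side it was 3.41-fold for Bcl2l11, at least 3.25-fold for Prkch, 3.19-fold for Ahnak, at least 3.03-fold for Rarg, 2.99-fold for Tlr13 and for Bmf, 2.98-fold for Rap1gap2 and at least 2.86-fold for Tmc4. Only 1 gene was higher and 8 were lower with the floor at the 75th percentile. With it at the 25th percentile the counts were 336 and 347, and with no floor 420 and 613.

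The gates form an order from c-Kit- low to c-Kit+ high, and signals were compared with it. Of 4014 genes whose range over the fractions was at least 2-fold, 1098 (27.4%) had signals ascending strictly in the order of the gates, as Gnl3, Mpo and Shmt1 did, and 902 (22.5%) had signals descending in it, as Hoxa9, Pirb, Ahnak and Niban1 did. Of the 22 other orders, the most frequent held 444 and 372 genes, both with c-Kit- low at an end, and the median one 37.5. An equal share is not expected of these orders, because c-Kit- low stands apart from the other fractions and the c-Kit+ fractions are close to each other. Leaving out the c-Kit- low array, 406 of 1571 genes ascended and 528 descended, and the next of the 6 possible orders held 226 and 207. The 3' to 5' ratios of Actb and lys ascend strictly in the order of the gates too, and those of Gapdh, phe, thr and dap do not.

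**Figure D3:**
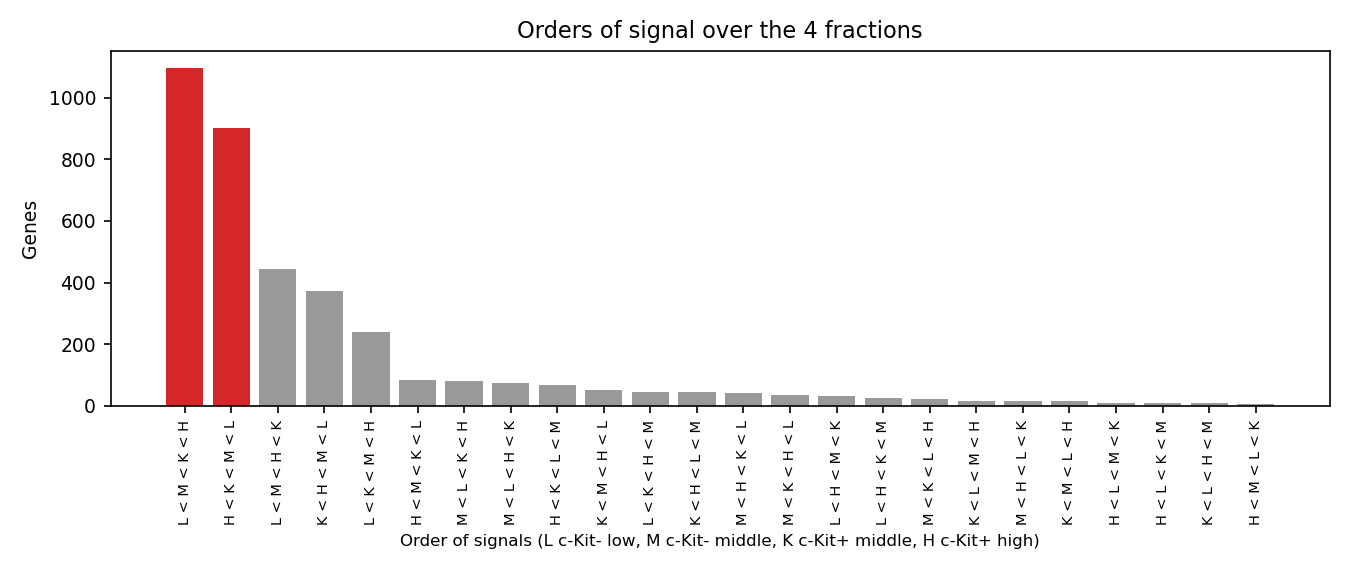
Number of genes following each of the 24 orders of the 4 fractions, from lowest to highest signal, over 4014 genes with a range of at least 2-fold. The red bars are the order of the gates (1098 genes) and its reverse (902).

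The remaining fixed lists were compared between the ends of the sort. The median was -0.27 (percentile 8.88) for posterior Hoxa genes and cofactors (6 measured), of which Hoxa5 was 3.16-fold higher and Hoxa9 3.69-fold lower in c-Kit+ high. It was 0.09 (percentile 55.6) for targets linked to Hoxa9 and Meis1 (14), -0.17 (percentile 8.18) for megakaryocyte genes (10) with Itgb3 3.64-fold lower, 0.00 (percentile 41.7) for marrow stroma and endothelium genes (8) with none past 2-fold, and -0.43 (percentile 3.09) for p53 targets (18) with the mTOR inhibitor gene Ddit4 19.0-fold lower. Glycolysis and hypoxia genes (24) had a median of 0.00 (percentile 31.9) with members going both ways, among them Egln3 13.3-fold and Ldha 2.80-fold higher and Pfkp 2.51-fold lower in c-Kit+ high. The median was 0.51 (percentile 90.6) for cholesterol synthesis genes (19), with Idi1 3.54-fold higher, 0.34 (percentile 82.4) for eosinophil, basophil and mast cell genes (8), and -0.34 (percentile 5.46) for ABC transporter genes (14), with Abca1 6.46-fold lower and Abcg2, the efflux pump of the side population, 2.11-fold higher. Primary granule genes had 4 of 8 higher (median 0.93, percentile 99.2), and without shared probe sets the median was 0.79 (percentile 96.5), within the range of random lists. The 3 measured sort and model genes had a median of 2.83 (percentile 99.96), the value of Gnl3. Kit was higher and Hoxa9 lower, and the markers of the sort were c-Kit and the NS-GFP reporter. Against c-Kit- middle in place of c-Kit- low the median was -0.18 for p53 targets, 0.11 for cholesterol synthesis genes, 0.68 (percentile 99.7) for eosinophil, basophil and mast cell genes and 1.15 for sort and model genes.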

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

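All tests in this part were chosen after the result they bear on was seen. Chance, other animals and other sorts cannot be weighed with 1 array per fraction.

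Probe sets matching several genes were not used in the comparisons, and some were very bright in c-Kit- low. The alpha globin probe set had a signal of 5173 there, against 383 in c-Kit- middle, 30.9 in c-Kit+ middle and a signal below the floor in c-Kit+ high. That of beta globin had 3294 and 217 in the c-Kit- fractions, a signal below the floor in c-Kit+ middle and 33.4 in c-Kit+ high, and that of immunoglobulin kappa 2648 and 251, a signal below the floor and 109. Of 638 such probe sets above the floor, 27 were at least 2-fold higher in c-Kit- low than in each other fraction.

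The globin, immunoglobulin, class II and Xist signal of the c-Kit- low array is the first pattern weighed. A shift in the scaling of that array is argued against, since the median of all genes between c-Kit- middle and c-Kit- low was -0.27 under the authors' scaling. Under the main scaling it was 0.03, but quantile normalization holds it near that value, so it cannot show a shift. An array made up mostly of female cells is argued against too, since the Y-linked genes had a median log2 ratio of 0.0081 (range 0.0078 to 0.90). A candidate explanation that stays open is an admixture of other blood cells within that sort. All 4 fixed lists of other lineages (erythroid, B cell, T and NK cell, MHC class II and dendritic cell) held at least 2 members at least 2-fold higher there than in each other fraction. Of their 38 measured members 16 were so, 5 were also above the floor in both c-Kit+ fractions and 0 stand in another list. Jchain, Cd74 and H2-Aa are among the 16 and belong to the pattern itself, so this count is not independent of it. The c-Kit sort would not remove such cells, and whether the low gate excluded cells without GFP was not given in the sources used here.

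The lower mature myeloid genes in c-Kit+ fractions are the second pattern. Cells bringing red cell and immunoglobulin signal are argued against as the whole cause, because the 46 myeloid list members that were lower had a median log2 ratio of -0.82 from c-Kit- low to c-Kit- middle (quartiles -1.11 to -0.39), against -3.55 for 6 markers of those cells. A 3' shift of the RNA stays open as a part of the pattern, since the 29 members that were lower in c-Kit+ middle had a median of -0.16 between the c-Kit+ fractions (quartiles -0.41 to 0.00) but were chosen by their low signal on that array, and the control ratios do not agree on a shift. Mature myeloid cells without the introduced genes cannot be told apart from differentiated leukaemia cells. Hoxa9 had a log2 ratio of -0.22 between the middle gates, and the probe set used for it may read only the gene of the animal. A difference in maturation that goes with c-Kit, which the design names, stays open as a hypothesis.

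The higher G2 and M phase genes at higher NS-GFP are the third pattern, and among c-Kit+ fractions other cells like those of the c-Kit- low array are argued against, since a median difference of 0.68 would need 37.6% of the RNA of c-Kit+ middle to come from them, while the 6 markers of those cells had at most 0.0083 to 0.076 of the signal that share would bring. Other kinds of cells are not covered, and the mast cell and basophil genes Cpa3 and Ms4a2 were 3.31-fold and 2.24-fold higher in c-Kit+ middle than in c-Kit+ high. Of the 8 measured genes of their list these 2 were lower in c-Kit+ high and 1, Prg3, was higher (at least 2.42-fold). The median of that list was -0.12 (percentile 8.1), within the range of random lists. Among c-Kit- fractions, dilution by female cells is argued against, since the Y-linked median was 0.0081 against 2.17, and dilution by male cells was not tested. Gates on GFP per cell that take up more cells late in the cycle are a candidate explanation that stays open. The G2 and M median exceeded the S phase median by 0.47 in c-Kit+ and by 0.57 in c-Kit- cells, with a difference of -0.45 between the middle gates. This excess cannot tell such gates from a larger share of dividing cells, since S phase medians were above 0 too (0.21 and 1.61). A link of division with nucleostemin promoter activity, which the design names, stays open and was not tested apart from such gates.

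The NS-GFP contrasts went opposite ways, by at least 2-fold each, for 7 genes, and the difference was not tested, with 1 array in each group. Of 9144 genes, 51 were higher and 68 lower with NS-GFP among c-Kit+ fractions, and 658 higher and 399 lower among c-Kit- fractions. Unrelated lists of these sizes would also share genes, so the 7 genes are not read as a pattern. H2-Aa (1.44 among c-Kit+ and -2.28 among c-Kit- cells), Mtg2 (1.1 and -1.50), Ryr1 (1.2 and -1.56), Saa3 (1.30 and -1.12) and Sbk1 (1.02 and -1.34) were higher with NS-GFP among c-Kit+ cells, and 3110021A11Rik (-1.02 and 1.09) and Zfp229 (-1.19 and 1.11) among c-Kit- cells.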

How the results depend on the processing

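The alternatives with c-Kit- middle in place of c-Kit- low and without the c-Kit- low array were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out within a group. In the alternatives run, no named gene past 2-fold changed direction, and of the list medians outside the range of random lists 1 changed sign, that of p53 targets between the c-Kit- fractions (-0.38, and 0.0028 with the floor at the 25th percentile, inside that range). Of 1020 alternative values of list medians, 948 kept their side of the range of random lists, 41 moved inside it and 31 moved outside it. Of the 491 alternative values of the 60 medians at the far ends of the random lists, 480 kept their side and 11 moved inside. Of 204 alternative counts and correlations 112 moved by more than their limit, and of 710 values of named genes 168 did. With the floor at the 75th percentile 75 of 98 named gene values moved, and with the mean of probe sets 50 moved and 48 did not. Each other setting moved 14 or fewer of them. Centring each array moved none of the counts. The floor and the fold threshold set the counts by their construction. The floor decides how much dim signal is counted, and the threshold decides the size of difference needed. For other moves the cause was not tested.

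The authors' scaling turned the split between higher and lower genes in all 4 comparisons, with 42.4%, 57.2%, 39.1% and 23.0% of genes past 2-fold higher against 54%, 40.0%, 50.2% and 54.8% (c-Kit+ high against c-Kit- low, c-Kit+ middle against c-Kit- middle, c-Kit+ high against c-Kit+ middle, c-Kit- middle against c-Kit- low). It turned the median of all genes from 0.09 to -0.08 in the first of these and from 0.03 to -0.27 in the last. Under it, 600 genes were higher in c-Kit+ middle than in c-Kit- middle, 377 were higher and 1265 lower in c-Kit- middle than in c-Kit- low, and 16 were set apart as higher in c-Kit+ high.

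With the floor at the 25th percentile, genes higher and lower numbered 3044 and 2620 (c-Kit+ high against c-Kit- low), 1520 and 1716 (c-Kit+ middle against c-Kit- middle), 1209 and 1163 (c-Kit+ high against c-Kit+ middle), 1937 and 1659 (c-Kit- middle against c-Kit- low), and 336 and 347 (set apart in c-Kit+ high). The NS-GFP contrasts had r = 0.185, and the eosinophil, basophil and mast cell median between the middle gates was 0.10. With the floor at the 75th percentile the counts were, in the same order, 1042 and 952, 148 and 285, 10 and 12, 370 and 282, and 1 and 8, with 694 and 558 genes ascending and descending with the gates. Medians were 0.00 for class II genes between the middle gates and, for interferon-stimulated genes, -0.17 in both c-Kit+ high and c-Kit- middle against c-Kit- low, all 3 within the range of random lists. With no floor the counts were 3572 and 3172, 2107 and 2283, 1768 and 1751, 2479 and 2215, and 420 and 613, with r = 0.0571 and a median of 0.51 for the eosinophil list.

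With the mean of probe sets, 228 genes were higher in c-Kit+ middle than in c-Kit- middle, 53 higher and 53 lower in c-Kit+ high than in c-Kit+ middle, and 14 and 25 set apart in c-Kit+ high. Between the c-Kit+ fractions the stem and progenitor median was -0.055 and the p53 target median -0.091. Without shared probe sets the class II median between the middle gates was 0.00. In the deposited log2 table, 24 genes were higher in c-Kit+ high than in c-Kit+ middle, 0 were set apart as higher in c-Kit+ high, and the interferon median between the c-Kit- fractions was -0.25, within the range of random lists. That table holds fewer genes.

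At 1.5-fold, higher and lower genes numbered, in the order above, 3260 and 2575, 1420 and 1449, 690 and 514, 1837 and 1627, and 315 and 230. At 4-fold they numbered 417 and 495, 33 and 128, 2 and 0, 105 and 47, and 0 and 0, with 295 and 325 genes in the order of the gates and its reverse. With c-Kit- middle in place of c-Kit- low, 538 genes were higher and 721 lower in c-Kit+ high, and the medians of T and NK cell and of oxidative phosphorylation genes were 0.00 and 0.094, those of G2 and M phase and of S phase genes 0.52 and 0.46, and those of immediate early and interferon-stimulated genes -0.23 and -0.22. Without the c-Kit- low array 406 genes ascended and 528 descended with the gates. Signal over background is the limit on dim genes, since a gene below the floor gives a bound or no value.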

Other observations

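The test of genes beside Bcl2l11 and Bmf among c-Kit+ fractions was planned before its result was seen. The tests of these genes against the c-Kit- fractions and of the second deposited table were chosen after.

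Genes of the BCL2 family differed along the sort. Bcl2l11, which encodes Bim, had signals of 1335, 549, 552 and 161 from c-Kit- low to c-Kit+ high, and Bmf had 489, 144, 83.3 and 27.9. Mcl1, a survival gene of myeloid cells, had signals of 5770, 4090, 2842 and 2358. Bcl2, another survival gene, was highest in c-Kit+ middle (708) and stood at 461 in c-Kit+ high.

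Lower BH3-only genes as a group are a candidate explanation for the low Bcl2l11 and Bmf signals of c-Kit+ high among c-Kit+ fractions only. There, 5 other BH3-only genes were above the floor in at least 1 of the c-Kit+ fractions. Their median log2 ratio between high and middle was -0.62, at percentile 0.07 of random lists. Hrk, at the floor in both, was left out, whereas random lists could hold such genes as 0, so the percentile can overstate the shift. Bbc3 had -0.96, Bik -0.81 (a bound), Pmaip1 -0.62, Bad -0.59 and Bid 0.16. Bik was above the floor in c-Kit+ middle alone, so its ratio could only be negative. The survival genes did not differ 1 way (Bcl2 -0.62, Mcl1 -0.27, Bcl2l2 0.01 and Bcl2l1 0.56). Against c-Kit- middle a lower group is argued against, with a median of -0.10 over 5 such genes (quartiles -0.25 to -0.09, and a median of -0.03 under the authors' scaling). Bcl2l11 had -1.77 and Bmf -2.37 there. The 5 genes were Bbc3, Pmaip1, Bad, Bid and, in place of Bik, Hrk. The median of -0.10 is the bound of Hrk, whose signal in c-Kit- middle was 16.5, near the floor. Against c-Kit- low a lower group stays open, with a median of -0.25 over 4 genes that spread widely (quartiles -0.59 to 0.05). Some of these genes stood high in c-Kit+ middle, where Pmaip1 (1.28), Bik (0.81, a bound), Bbc3 (0.69) and Bad (0.50) were above c-Kit- middle. Bbc3 and Pmaip1 also stand in the list of p53 targets, so these lists are not independent, and the pattern rests on 1 array per fraction.

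The second deposited table leaves out most probe sets without its rule being stated. A filter on the dimmest array is a candidate explanation, since 99.8% of 9069 probe sets with a signal of at least 100 on every array were kept and 0 of 15 that reached 500 on 1 array and lay under 5 on another. Of genes past 2-fold with 1 array at the floor, it keeps 11.4% for c-Kit+ high against c-Kit- low, 7.87% for c-Kit+ middle against c-Kit- middle, 5.19% for c-Kit+ high against c-Kit+ middle and 11.7% for c-Kit- middle against c-Kit- low. Most genes past 2-fold with a fraction at the floor are thus absent from it.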
